A study of Mus musculus with 10 samples.

How the data were processed

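RNA from 10 pooled samples of mouse abdominal aorta, 5 infrarenal and 5 suprarenal, was measured on 1 array each. Per the labels' protocols, RNA was extracted from the artery segments, between 0.34 and 0.54 µg was amplified into biotin-labelled cRNA, and the label was stained with Cy5-streptavidin. The deposited values are linear intensities that the authors had scaled per array, with medians between 1.001 and 1.003 as read from the values. The scanner, the background correction and the scaling method are not given in the sources used here. Of the deposited intensity values, 1968 were missing and 1755 were at or below 0.

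Intensities below a floor of 0.0278, the percentile 1 of all positive values, were raised to it, which set 5350 values to the floor (-5.17 on the log2 scale), and log2 was taken. No further normalization was applied, since the array medians lay within 0.1 log2 units. A probe needed at least 3 values in each region, which left 36061 of 36227 probes and dropped 166. Log2 differences of dim probes are compressed by the floor and noisier, and scaling to the median assumes that most probes do not differ.

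Gene names came from the platform annotation, updated through Entrez identifiers with the RefSeq gene table of GRCm38.p6, used only for names. A single symbol was listed for 21615 probes, of which 21487 matched by Entrez identifier, several for 681 and none for 13931. These gave 17991 genes. No coordinates are given, because the sources name no genome build. The probe with the highest mean over all arrays stood for a gene.

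The regions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) with the pool as a block, and p-values were adjusted by Benjamini-Hochberg over all probes, at a threshold of 0.05. The tests are two-sided. The pairing comes from the design: both parts of a pool come from the same animals. The deviations of paired arrays from their region means correlated at 0.248, -0.008, 0.021, -0.244 and -0.184 in pools 1, 6, 8, 11 and 12. The fit with no replicate block also called 0 probes.

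The 38 gene lists, with 944 entries of which 837 matched a gene, were written before the data were examined, as were the design, the rule for named genes and the alternatives, apart from the additions named below. Lists were tested with camera at a preset correlation of 0.01, with 164 genes left out for missing values, and with an estimated correlation and with fry as alternatives. A list's direction is the sign of its mean difference. Named genes were the 12 largest differences on each side among genes past the threshold with the same sign in all pools, filled up to 6 on a side by smallest p where fewer passed. Per list they were up to 4 passing members, or the 2 of smallest p, and Apoe was added. Any other gene named in the closing section was chosen after its values were seen.

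Other alternatives were quantile normalization, an offset of 0.2701 (percentile 25 of positive values) in place of the floor, the dimmest 30% of probes left out, each pool left out in turn, no variance trend, array weights, RNA input as a covariate, and all probes of a gene averaged. Covariates for brown adipocyte, skeletal muscle and sympathetic neuron scores, and the estimated correlation under the other alternatives of the list test, were added after the data were seen. The scripts were tested on simulated data of 35714 probes with 200 changed. Of 50 probes per size, 6%, 44%, 82% and 88% were recovered at 0.5, 1, 2 and 3 log2 units, with 11 false calls, and 0 lists were called where no change was simulated. The simulation drew probes independently, so it does not test the list calls against correlated genes.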

Results

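Gene expression was measured in the abdominal aorta of male ApoE-/- mice, which lack apolipoprotein E and develop high plasma cholesterol and atherosclerosis. The mice were 14 weeks old. The aortas of 2 mice made a pool, and each of 5 pools was divided into an infrarenal part, below the kidney arteries, and a suprarenal part, above them. This gave 5 infrarenal and 5 suprarenal arrays, numbered by pool as 1, 6, 8, 11 and 12. Each array listed 36227 probes, read in a single colour, as intensities scaled to an array median between 1.001 and 1.003. Any pair of arrays correlated with r between 0.962 and 0.975 across probes, which are not independent replicates. The number of arrays limits the precision. The median half-width of the 95% interval of a regional difference was 0.36 log2 units over all probes and 0.25 over the brighter part of them.

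The knocked-out gene was looked at first. The Apoe probe read -4.14 ± 0.93 log2 units (SD, n = 5) in infrarenal and -3.58 ± 0.74 (SD, n = 5) in suprarenal aorta. It lay among the dimmest 30% of probes, above the floor of -5.17 on all 10 arrays. Which part of the gene the probe covers is not given in the sources used here, and wild-type aorta was not analysed here.

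The comparison asked which genes are expressed differently below and above the kidneys in the same animals. Of 38 gene lists, 6 passed the set test, all lower in infrarenal aorta: genes of oxidative phosphorylation, of the tricarboxylic acid cycle and fatty acid oxidation, of adipocytes, of macrophages, of cholesterol and lipid handling, and of oxidative stress. The mean log2 differences of these lists, infrarenal minus suprarenal, lay between -0.48 and -0.19. The median over all genes was -0.049, and random lists of matched brightness had medians between -0.117 and -0.0695. No single gene passed the test. None of the 6 list calls held with an estimated correlation between genes (adjusted p = 0.957 for each), and the number of calls was not above what other splits of the arrays gave. With no replicate block, where 6 lists also passed, 70 of 100 splits gave as many, the real one included. In the paired fit, 12 of the 16 splits that part every pool gave as many.

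Of 36061 probes tested with limma, 0 were higher and 0 were lower in infrarenal aorta after adjustment. The smallest adjusted p was 0.11, for a probe without a gene name. At an unadjusted p under 0.05 there were 2726 probes, 1101 higher and 1625 lower in infrarenal aorta, where 1803 would be expected by chance. There were 1475 without pool 6 and 1801 without pool 8, both below that number, and 3931 without pool 12. Among the other splits of the arrays that part every pool, counts ran from 744 to 3699, with most below 2726 and several above. The 3699 came with the regions of pool 12 turned, and exchanged labels of that pool stay open. With the regions of pools 1 and 11 turned, the count was 2938. The excess over 1803 therefore does not set the regions apart from splits that part every pool. The balance of the regions turned to 1132 higher and 929 lower after quantile normalization, 1346 and 977 with no variance trend, and 1079 and 722 without pool 8. After quantile normalization 1 probe, higher in infrarenal aorta, passed. The sign was the same in all 5 pools for 3280 probes, or 9.1%, against 6.25% by chance. This share was not compared with other splits of the arrays. In simulated arrays of the same spread, 44% of 50 probes changed by 1 log2 unit were recovered, and 6% of those changed by 0.5.

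The named genes of smallest p with the same sign in all 5 pools are given as values that did not pass (adjusted p = 0.639 for each). Higher in infrarenal aorta were Zkscan16, a zinc finger gene, with a log2 difference of 0.59 ± 0.10 (SE, n = 5 pools), and the olfactory receptor gene Olfr420 with 0.93 ± 0.17. Exoc1, a subunit of the exocyst that tethers secretory vesicles, differed by 0.53 ± 0.11. The less characterised 6430550D23Rik, Gm8624 and 4930583I09Rik differed by 0.60, 0.77 and 0.80. A second, dimmer Zkscan16 probe differed by 0.077. Lower in infrarenal aorta was Cd59a, an inhibitor of the complement membrane attack complex, with -0.79 ± 0.14. Prkaca, a catalytic subunit of protein kinase A, differed by -0.81 ± 0.17. Dnm1l, which divides mitochondria, differed by -0.47 ± 0.09 and Rab5a, a regulator of early endosomes, by -0.41 ± 0.08. Fkbp3 and Bsdc1 differed by -0.49 and -0.43.

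**Figure D1:**
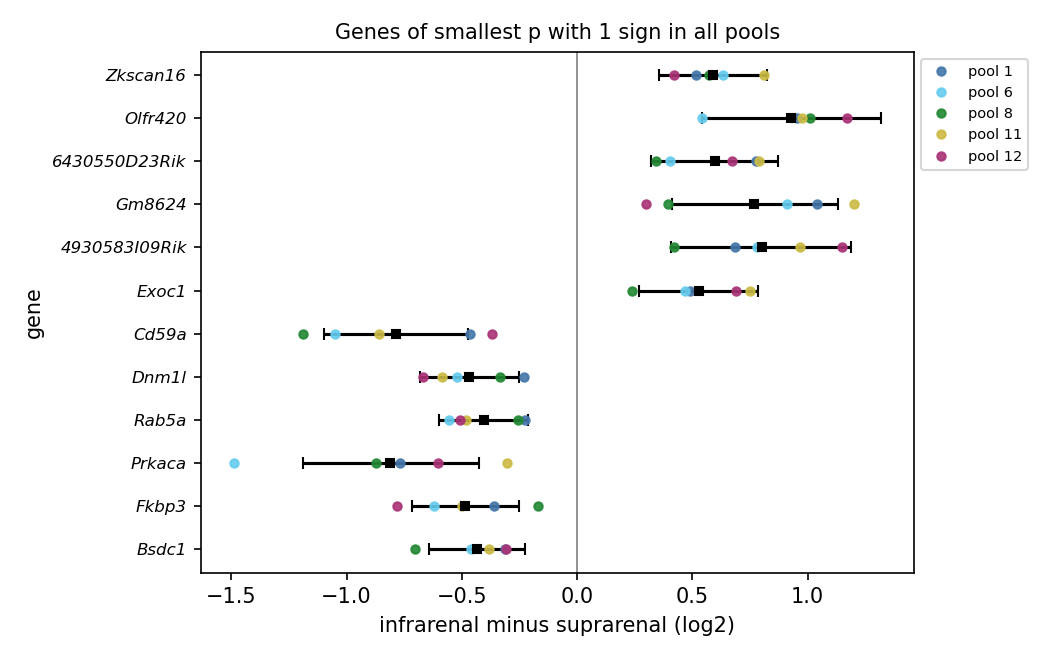
Infrarenal minus suprarenal log2 differences (x axis) of the 12 genes of smallest p with the same sign in all pools (y axis), with a square for the fitted difference, bars for its 95% interval and a coloured point for each of the 5 pools. Zkscan16 averages 0.59 and Cd59a -0.79, and none of the 12 passed after adjustment.

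Genes of mitochondrial respiration were lower in infrarenal aorta as a group. Of 48 oxidative phosphorylation genes, 47 had negative differences, with a list mean of -0.36 ± 0.46 (SD, n = 5 pools) and an adjusted p of 9.34e-10 by limma's camera (0.957 with an estimated correlation). None passed singly, over all probes or adjusted over the list alone. The complex I subunit genes Ndufa9 and Ndufb3 differed by -0.42 ± 0.14 and -0.41 ± 0.13 (SE). Of 28 genes of the tricarboxylic acid cycle and fatty acid oxidation, 27 were negative, with a mean of -0.48 ± 0.71 (SD, n = 5 pools) and an adjusted p of 1.16e-05 (0.957 with an estimated correlation). Fh1, which encodes fumarate hydratase, differed by -0.52 ± 0.20 and Pdha1, of the pyruvate dehydrogenase complex, by -0.58 ± 0.23 (SE). The oxidative phosphorylation list ranged by pool from -1.04 in pool 6 to 0.14 in pool 12, and the other list from -1.44 to 0.39 in the same pools. Without pool 6 the means were -0.20 and -0.24, and with the brown adipocyte score as a covariate -0.17 and -0.17, and both lists still passed at the preset correlation. With an estimated correlation neither passed, with an adjusted p of 0.996 without pool 6 and 0.944 with the score.

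Adipocyte genes moved with these lists. All 26 general adipocyte genes measured had negative differences, with a mean of -0.40 ± 0.84 (SD, n = 5 pools) and an adjusted p of 0.0153 (0.957 with an estimated correlation). Lpl, lipoprotein lipase, differed by -0.56 ± 0.20 and Slc2a4, the insulin-responsive glucose transporter, by -0.57 ± 0.29 (SE), and neither passed. This call ended without pool 1, 6 or 11 (adjusted p = 0.0643, 0.953 and 0.0611), without dim probes (0.0631) and with the sympathetic neuron or brown adipocyte score as a covariate (0.108 and 0.903). The list mean was -0.094 without pool 6, -0.055 with the brown adipocyte score and -0.68 without pool 12. Brown adipocyte markers did not pass (20 of 24 negative, mean -0.44 ± 0.997, SD, n = 5 pools; adjusted p = 0.217), but passed after quantile normalization (-0.38), without pool 12 (-0.79) and with a skeletal muscle score as a covariate (-0.53). With an estimated correlation these 3 calls were lost (adjusted p = 0.983, 0.685 and 0.795). Among them Fabp3, a fatty acid carrier, differed by -1.09 ± 0.28 and Elovl3, a fatty acid elongase, by -1.52 ± 0.68 (SE). The brown adipocyte score was 1.70 on suprarenal array 12 and between 3.12 and 3.45 on the other suprarenal arrays.

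Macrophage and monocyte genes were lower in infrarenal aorta in 23 of 27 cases, with a list mean of -0.19 ± 0.21 (SD, n = 5 pools) and an adjusted p of 0.000615 (0.957 with an estimated correlation). C1qc and C1qb, which encode chains of complement C1q, differed by -0.42 ± 0.09 and -0.33 ± 0.08 (SE) and were lower in 5 of 5 pools. No member passed singly, and without pool 12 the list had an adjusted p of 0.0502 and a mean of -0.13. After quantile normalization the mean was -0.12 and the list passed (adjusted p = 0.983 with an estimated correlation). T and B cell markers had a mean of -0.081 (20 of 24 negative, adjusted p = 0.564). Cathepsin and plasminogen genes had a mean of -0.10 (adjusted p = 0.302), with Ctss at -0.26 and Ctsb at -0.26. Chemokine, cytokine and adhesion genes had a mean of -0.037 (adjusted p = 0.975), with the B cell chemokine gene Cxcl13 at -0.69 ± 0.15 and Ccl9 at -0.40 ± 0.12 (SE). Neutrophil and mast cell markers had a mean of 0.011 (adjusted p = 0.627). The mast cell genes Ms4a2 and Kit differed by 0.54 and 0.48, while a dimmer Kit probe differed by 0.039.

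Genes of cholesterol and lipid handling were lower in infrarenal aorta in 5 of 5 pools, with 20 of 22 members negative, a mean of -0.28 ± 0.21 (SD, n = 5 pools) and an adjusted p of 0.000539 (0.957 with an estimated correlation). Over all probes 0 members passed, and 3 passed adjusted over the list alone, Idi1, Pla2g7 and Abcg1, the last named after its value was seen. Idi1, an enzyme of sterol synthesis, differed by -0.43 ± 0.11 and Pla2g7, a phospholipase carried on lipoproteins, by -0.59 ± 0.16 (SE). Abcg1, a cholesterol exporter, differed by -0.36 ± 0.10 (SE). Oxidative stress genes were also lower in 5 of 5 pools, with 26 of 28 negative, a mean of -0.22 ± 0.17 (SD, n = 5 pools) and an adjusted p of 0.00126 (0.957 with an estimated correlation). The metallothionein gene Mt1 differed by -0.30 ± 0.08 and Gclm, of glutathione synthesis, by -0.40 ± 0.12 (SE), and neither passed. After quantile normalization the oxidative stress mean was -0.12, with an adjusted p of 0.047 (0.983 with an estimated correlation).

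**Figure D2:**
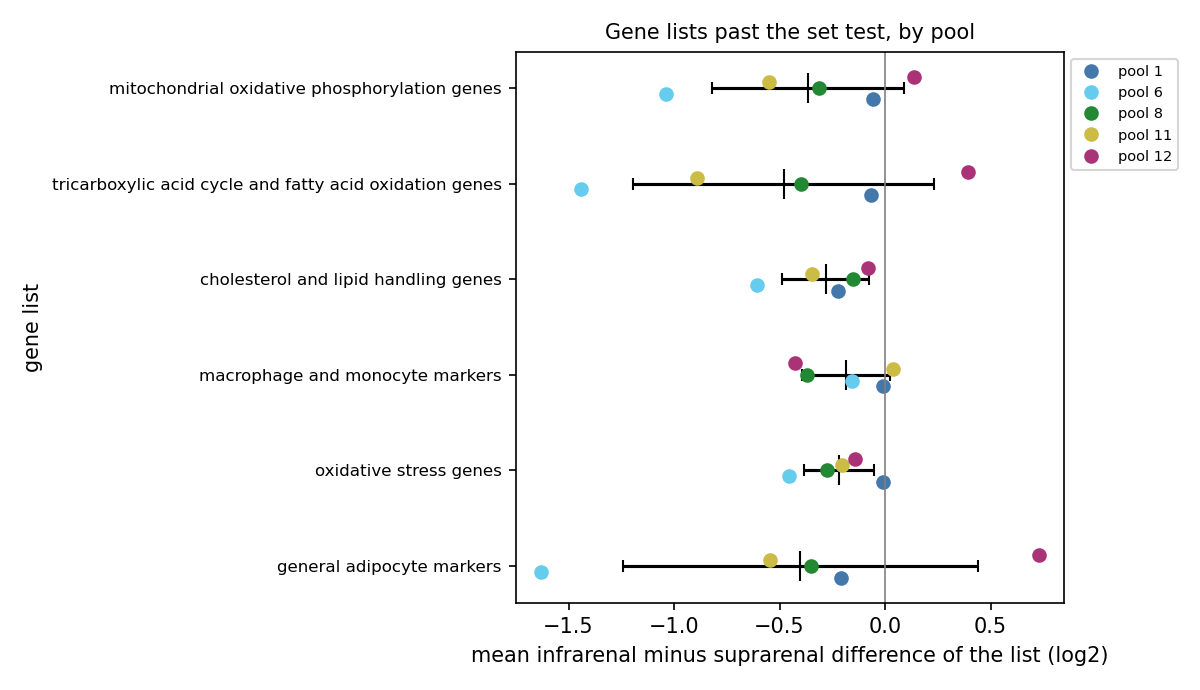
Mean infrarenal minus suprarenal log2 difference (x axis) of each gene list past the set test (y axis), with a coloured point for each of the 5 pools, a tick for their mean and bars for their SD. Pool 12 lies above 0 for oxidative phosphorylation (0.14) and general adipocyte markers (0.73), and all pools lie below 0 for the cholesterol and oxidative stress lists.

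Hox genes, which pattern the body from head to tail, did not pass as lists on all arrays. Paralogue groups 1 to 8 had a mean of -0.17 ± 0.21 (SD, n = 5 pools), with 17 of 21 negative and an adjusted p of 0.161. Hoxa5 differed by -0.39 ± 0.12 and Hoxc6 by -0.36 ± 0.11 (SE). Paralogue groups 9 to 13 had a mean of 0.22 ± 0.67 (SD, n = 5 pools), with 8 of 13 positive and an adjusted p of 0.564. Hoxd10 and Hoxc13, the members of smallest p, differed by -0.27 and -0.16, against the sign of the list mean. Hoxa11 and Hoxa10, named after their values were seen, differed by 0.80 ± 0.60 and 0.50 ± 0.42 (SE), and neither passed. In all, 5 of the 13 members were negative. Pools 1, 6, 8 and 11 had differences of 0.17, 0.38, 0.55 and 0.88 for this list, and pool 12 had -0.88. Without pool 12 both Hox lists passed (-0.23 and 0.50), among 11 lists in all, and none of the 11 passed with an estimated correlation (adjusted p = 0.685 for both Hox lists). Groups 1 to 8 also passed after quantile normalization (-0.15) and with the skeletal muscle score (-0.18), but not with an estimated correlation (adjusted p = 0.983 and 0.795). Other patterning factors had a mean of 0.043 (adjusted p = 0.564), with Tcf21 at -0.25 and the dim Emx2 at 1.42.

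Lists of the vessel wall did not pass on all arrays. Smooth muscle contractile genes had a mean of 0.041 (13 of 23 positive, adjusted p = 0.114), with Pln, a regulator of the calcium pump, at 0.27 ± 0.10 and Lmod1 at 0.26 ± 0.12 (SE). This list passed, higher in infrarenal aorta, after quantile normalization (0.14), without dim probes (0.041), without pool 12 (0.14) and with the skeletal muscle score (0.062). With an estimated correlation it passed under none of these (adjusted p = 0.983, 0.978, 0.685 and 0.795). Collagen genes had a mean of -0.0025 (adjusted p = 0.659), with Col5a3 at -0.28 and Col10a1 at 0.26. Elastic fibre genes had a mean of -0.034 (adjusted p = 0.975), with Loxl3 at 0.19 and Ltbp4 at -0.23. Proteoglycans and matricellular proteins had a mean of -0.11 (adjusted p = 0.659), with Prelp at -0.30 and Gpc3 at -0.36. Matrix metalloproteinases and their inhibitors had a mean of 0.0063 (adjusted p = 0.564), with Mmp11 at 0.31 ± 0.09 (SE) and Mmp19 at -0.30. Adventitial fibroblast markers had a mean of -0.13 (adjusted p = 0.302), with Ackr3 at -0.35 and Thy1 at -0.29. Endothelial markers had a mean of -0.029 (adjusted p = 0.975), with Cldn5 at -0.37, and lymphatic endothelial markers -0.028 (adjusted p = 0.975), with Lyve1 at -0.21.

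Signalling lists did not pass on all arrays either. Bone and calcification genes had a mean of -0.046 (adjusted p = 0.886), with Alpl, the tissue alkaline phosphatase, at -0.49. TGF-beta signalling genes had a mean of -0.074 (adjusted p = 0.659), with Inhba at 0.34 and Tgfb1 at -0.17. Wnt signalling genes had a mean of -0.087 (adjusted p = 0.975), with Dkk3 at -0.24 and Wnt6 at -0.20. Renin-angiotensin genes had a mean of 0.030 (adjusted p = 0.975), with Mme at -0.46 and Agt, angiotensinogen, at -0.37. Vasoactive receptors and ligands had a mean of -0.0038 (adjusted p = 0.975), with P2ry2 at -0.49. The brighter Nos1 probe differed by 0.26 and the dimmer one by -0.58. Immediate early and heat shock genes had a mean of 0.025 (adjusted p = 0.627), with Hsph1 at -0.31, and passed without pool 12 (0.11; adjusted p = 0.685 with an estimated correlation). Cell cycle genes had a mean of -0.050 (adjusted p = 0.975), with Mcm6 at -0.15, and circadian clock genes -0.074 (adjusted p = 0.886), with Arntl at -0.35.

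Markers of neighbouring tissues varied between arrays of the same region, and none of these lists passed on all arrays. Skeletal muscle markers differed by -2.59 in pool 12 and 1.87 in pool 11, with a mean of -0.15 ± 1.73 (SD, n = 5 pools; adjusted p = 0.937) and Tnnt1 at -1.02 ± 0.44 (SE). Adrenal medulla and sympathetic neuron markers differed by -2.53 in pool 1 and 1.74 in pool 12, with a mean of -0.19 ± 1.84 (SD, n = 5 pools; adjusted p = 0.896) and Dbh, of noradrenaline synthesis, at -0.18. Skeletal muscle markers passed with the brown adipocyte score as a covariate (-0.88), sympathetic neuron markers without pool 12 (-0.68) and Schwann cell markers without pool 8 (-0.33). With an estimated correlation these calls were lost (adjusted p = 0.944, 0.804 and 0.974). Schwann cell markers had a mean of -0.13 (adjusted p = 0.503), mesothelial markers -0.23 (adjusted p = 0.756) and erythroid markers -0.18 over 4 genes (adjusted p = 0.503). Kidney markers had a mean of 0.14 (adjusted p = 0.253), adrenal cortex markers 0.0011 (adjusted p = 0.659) and liver and pancreas markers 0.066 (adjusted p = 0.627). The mean, the median and the direction of the set test, which compares a list with all other genes, did not share a sign for 8 lists: other patterning factors, collagen, metalloproteinases, bone, Wnt, vasoactive, endothelial and skeletal muscle.

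**Figure D3:**
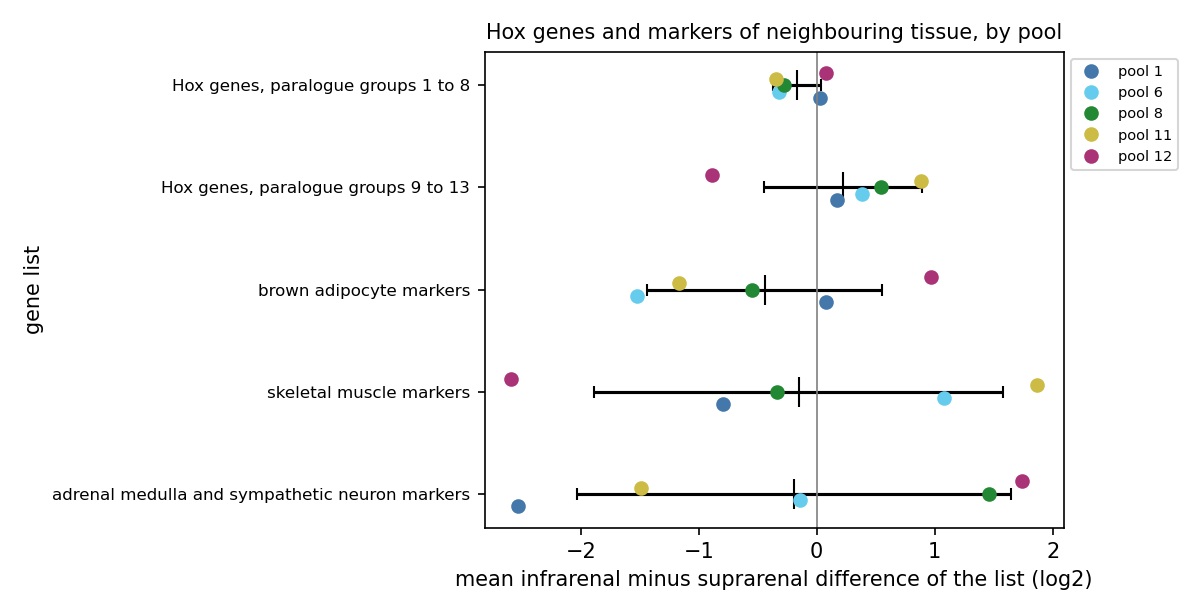
Mean infrarenal minus suprarenal log2 difference (x axis) of the Hox lists and of markers of fat, muscle and nerve (y axis), with a coloured point for each of the 5 pools, a tick for their mean and bars for their SD. In pool 12 the Hox 9 to 13 list is at -0.88, brown adipocyte markers at 0.97 and skeletal muscle markers at -2.59.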

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

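The tests of explanations in this part were chosen after the results were seen, except the comparison with random lists of matched brightness. Among 254 sets of 5 arrays from 1 region, for list scores and named genes, 17 had an array far from the other 4, where chance gives about 13.

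Infrarenal array 12 had a score of 0.064 log2 units for Hox genes of paralogue groups 9 to 13, against 0.69 to 0.93 on the other infrarenal arrays, and suprarenal array 12 read 0.95. Exchanged labels of the 2 pool 12 arrays may be a cause: over 17847 bright probes the pool 12 differences correlated at -0.421 with the mean of the other 4 pools, while pool 1 gave -0.137 and the other 3 gave 0.128 to 0.40. Of the 11 lists that passed without pool 12 (none with an estimated correlation, smallest adjusted p = 0.685), 9 had the other sign in pool 12, and the 2 that kept it did so by less than the SD of the other pools. This count first used the lists that passed on all arrays, which decided nothing, and was changed after both results were seen. The macrophage list just missed the 11 (camera adjusted p = 0.0502 without pool 12). It read -0.425 in pool 12, beside -0.00956, -0.158, -0.372 and 0.0356 in pools 1, 6, 8 and 11. An exchange would turn the sign of its pool 12 value. A line through the other 4 pools predicted a Hox difference of 0.104 (95% interval -2.36 to 2.57) from brown fat markers and -0.0618 (-1.94 to 1.82) from skeletal muscle markers, where -0.88 was measured. The correlation and the 11 lists have the values an exchange needs, but an exchange is not shown. The macrophage list cannot decide, because its pool 12 value helped it pass on all arrays and the other pools differ in sign. Fat and muscle stay open because 4 pools give wide intervals, and tissue around the vessel moves with pool 12 too. The level at which the vessel was divided stays untested, and no array was regrouped.

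Suprarenal array 12 stood low for oxidative phosphorylation genes, at 5.88 against 6.47 to 6.68, for brown adipocyte markers, at 1.7 against 3.12 to 3.45, and for Lpl, at 5.69 against 6.51 to 6.76. For the lower infrarenal level of oxidative phosphorylation genes, a scaling difference of bright genes is argued against as the whole cause only: the list mean of -0.36 lay below all 1000 random lists of matched brightness, whose lowest was -0.189, but their median was -0.11 and quantile normalization moved the list mean to -0.242. The part that followed brown adipocyte markers across the pools was -0.191 (95% interval -0.312 to -0.0697, from the slope only). That interval takes the mean brown adipocyte difference of -0.44 ± 0.997 (SD over the pools) as known, so it does not settle the sign of the part. The whole difference was -0.365 ± 0.204 (SE). With the brown adipocyte score as a covariate, -0.174 ± 0.0853 (SE, 95% interval -0.446 to 0.0975) was left. The list then passed the set test at the preset correlation (adjusted p = 1.44e-05) but not with an estimated one (adjusted p = 0.944). The interval of what was left includes 0, but the difference was already imprecise before the score was added (SE 0.204). The interval therefore cannot tell a difference removed by brown fat from a lack of precision. Brown fat may be part or the whole of the cause, and a difference between the regions themselves stays open.

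For the lower infrarenal level of macrophage genes, 1 of 1000 random lists of matched brightness reached the list mean of -0.19. Their median was -0.0807 and the lowest -0.252, and scaling of bright genes is not decided. The part that followed brown adipocyte markers across the pools was 0.0462, of the other sign (95% interval -0.0993 to 0.192, again from the slope only). In pool 12 the brown list was at 0.97 with macrophage genes at -0.425. With the score as a covariate the difference was -0.232 ± 0.103 (SE), and the list passed at the preset correlation (adjusted p = 0.000141) but not with an estimated one (adjusted p = 0.944). The 95% interval of that difference, -0.561 to 0.0967, includes 0. The difference was already imprecise before the score was added (-0.186 ± 0.0929, SE), so that interval cannot decide. The part that followed brown adipocyte markers had the other sign, and its interval did not reach -0.186. Adding the score made the difference larger, which restates that sign and is not separate support. The interval of that part leaves out the error of the difference itself and that of the mean brown adipocyte difference. Brown fat as the whole cause is therefore not decided. A difference between the regions may remain.

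The other arrays that stood apart are given as values. Suprarenal array 8 had a T and B cell score of 0.759 against 0.232 to 0.349, and suprarenal array 1 an erythroid score of 4 against 2.22 to 2.65. Zkscan16 read 0.569 on suprarenal array 12 against 0.0186 to 0.165. On suprarenal array 6, Prkaca read 1.83 against 0.549 to 0.826, Hoxc6 1.93 against 1.34 to 1.4, and Col10a1 -1.44 against -1.1 to -1. Infrarenal array 8 had a bone and calcification score of 1.47 against 1.59 to 1.63. Infrarenal array 12 had a chemokine, cytokine and adhesion score of 1.14 against 1.32 to 1.38, and Alpl read 2.08 there against 1.28 to 1.5. On infrarenal array 1, Pln read 2.52 against 1.72 to 1.95, Agt 1.26 against 0.537 to 0.707, Fcer2a 1.43 against 0.942 to 1.07, and Fech 5.04 against 4.22 to 4.38.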

How the results depend on the processing

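The covariate settings, and the estimated correlation under other alternatives, were chosen after seeing the data. The 0 probes called in the paired fit stayed 0 with no replicate block and under every other alternative, 0 to 0 when each pool was left out, except quantile normalization, which called 1. The 6 list calls became 0 with an estimated correlation and 0 with fry, and 11 without pool 12, with a range of 5 to 11 when each pool was left out. With no replicate block 6 lists passed, and the block changed no call. With an estimated correlation 0 lists passed under each of 13 alternatives, with adjusted p from 0.685 to 0.999. The cause of the change after quantile normalization and without pool 12 was not tested; estimating the correlation widens the error of lists whose genes move together. The 89 named genes kept their sign in all 1061 values, and none passed. Part of this was fixed in advance: genes picked for the same sign in all 5 pools cannot turn when a pool is left out. The others were picked for small p in these data, apart from Apoe, and genes were not run with the score covariates. The means of the 6 lists that passed kept their sign in every alternative run. Part of this was fixed too: dropping the block, estimating the correlation or using fry leaves a mean unchanged. The same holds for a gene with no missing values when the block or the variance trend is dropped. The direction of the set test differed from that on all arrays in 79 of 566 list values, 1 of them for a list that had passed: general adipocyte markers with the brown adipocyte score. Camera compares a list with the other genes, while fry, included here, tests the list by itself. Part of the 79 may come from that change of test. Quantile normalization and the skeletal muscle score each gave 9 lists, adding Hox groups 1 to 8, smooth muscle and brown adipocyte lists. Leaving out dim probes added smooth muscle, leaving out pool 8 Schwann cell, and the brown adipocyte score skeletal muscle. Without pool 12 both Hox lists, smooth muscle, brown adipocyte, sympathetic neuron and immediate early lists were added. The general adipocyte call was lost without dim probes (adjusted p = 0.0631), without pool 1, 6 or 11 and with the brown adipocyte or sympathetic neuron score (0.903 and 0.108), and the macrophage call without pool 12. A list used as a covariate was not tested against itself. Depth over background is unknown, and dim probes are limited by the floor. 

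Lists that had not passed and turned sign took these mean log2 differences. After quantile normalization, elastic fibre 0.051, collagen 0.067, vasoactive 0.030, endothelial 0.051, lymphatic endothelial 0.044, adrenal cortex -0.049. With the offset, patterning factors -0.0060, adrenal cortex -0.053, liver and pancreas -0.00057. Without dim probes, patterning factors -0.044, metalloproteinases -0.010, renin-angiotensin -0.0091, neutrophil and mast cell -0.0072, skeletal muscle 0.017, adrenal cortex -0.097, liver and pancreas -0.041. With the brown adipocyte score, Hox 9 to 13 -0.033, smooth muscle contractile -0.061, metalloproteinases -0.091, renin-angiotensin -0.049, neutrophil and mast cell -0.077, sympathetic neuron 0.054, immediate early and heat shock -0.022. With the skeletal muscle score, vasoactive 0.0097, adrenal cortex -0.018. With the sympathetic neuron score, metalloproteinases -0.0083. With probes averaged, neutrophil and mast cell -0.0059. Lists that turned sign when 1 pool was left out had means over these ranges: lymphatic endothelial -0.10 to 0.065, skeletal muscle -0.66 to 0.46, adrenal cortex -0.14 to 0.12, sympathetic neuron -0.68 to 0.39, Schwann cell and myelin -0.33 to 0.070, liver and pancreas -0.035 to 0.16, immediate early and heat shock -0.022 to 0.11, smooth muscle contractile -0.016 to 0.14, metalloproteinases -0.085 to 0.081, neutrophil and mast cell -0.076 to 0.068, kidney -0.015 to 0.24, bone and calcification -0.078 to 0.0031, renin-angiotensin -0.032 to 0.14, T and B cell -0.14 to 0.039, chemokines and adhesion -0.11 to 0.039, collagen -0.037 to 0.046, TGF-beta signalling -0.13 to 0.0038, vasoactive -0.037 to 0.084, endothelial -0.071 to 0.055, cell cycle -0.088 to 0.0019. The cause was not tested.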

Other observations

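The splits of the arrays were set before their results were seen. The genes named in this part were chosen after their values were seen, apart from Arntl and Ciart.

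Some clock genes varied between pools in both regions. Arntl, the clock activator, had an SD of 1.66 over infrarenal and 1.41 over suprarenal arrays and a regional difference of -0.35 ± 0.13 (SE, n = 5 pools), which did not pass. It read 3.34 and 3.48 log2 units in infrarenal and suprarenal aorta of pool 6 and 2.29 and 2.31 in pool 8. In pools 1, 11 and 12 it lay between -0.45 and 0.54, and the regions of pool 1 differed by -0.753. Ciart, a repressor of the clock, ran the other way, with -0.17 and -0.57 in pool 6 and values between 2.25 and 2.90 in pools 1, 11 and 12. Per2, another repressor, read 0.64 and 0.52 in pool 6 and between 1.95 and 2.56 in those 3 pools. The dim Npas2, an activator related to Clock, had SDs of 1.40 and 1.10 and read -0.57 and -0.74 in pool 6 and -4.16 and -2.70 in pool 11. SDs were 0.907 and 0.862 for Hlf, against 0.157 and 0.246 for Cry1, 0.182 and 0.190 for Cry2 and 0.296 and 0.261 for Clock. The time of day of harvest is not given in the sources used here.

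Scores of the nerve and muscle lists spread widely between arrays. The sympathetic neuron score ranged from 0.16 to 1.72 over infrarenal and from -0.027 to 2.69 over suprarenal arrays, and the skeletal muscle score from 1.37 to 2.73 and from 0.52 to 4.12. Npy, a sympathetic neuropeptide, read 6.33 and 5.54 on suprarenal arrays 1 and 11 and 5.60 and 5.19 on infrarenal arrays 8 and 12, against 0.0032 on suprarenal array 12. Th, tyrosine hydroxylase, read 5.10, 4.09, 4.02 and 3.89 on the same 4 arrays. Acta1, skeletal muscle actin, read 7.25 on suprarenal array 12 and 6.64 on infrarenal array 8. Myl2, of slow muscle, was high on suprarenal arrays only, at 3.31 and 2.11 on arrays 12 and 8, and at most 0.56 on infrarenal arrays. Alas2, of haem synthesis in red cells, read 6.32 and 6.74 on both arrays of pool 1 and at most 5.44 on the others.

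With 0 probes called, every split of the arrays gives at least as many (100 of 100), so the splits decide nothing about that count. The highest other value was 327, in a split that parts only 3 pools, and 19 among the splits that part all 5. For the lists, the fit with no replicate block has the same form in every split. It gave 6 or more lists in 70 of 100 splits, with 6 for the real one and up to 16 in another, so chance cannot be excluded for the list count. In the paired fit 69 of 100 splits gave as many, with up to 14 in another, but only 12 of those 100 part all 5 pools and many of the others repeat the same fit. Among the 16 splits that part all 5 pools, 12 gave at least 6 lists. Those splits are too few for a share under 0.05, and the highest other value was 14, reached when the regions of pool 12, or of pools 1 and 12, were turned.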
